A study of Homo sapiens with 4 samples.

How the data were processed

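RNA of 4 samples of primary ovarian cancer cells, 2 labelled control and 2 labelled GSK126, had been amplified as a whole-transcriptome product and hybridised to single-channel arrays, per the labels. The deposited values are on a log2 scale and were made by the authors with the RMA method of the R package oligo, per the submitters' processing notes, which give no version. RMA subtracts a modelled background, quantile-normalizes the arrays and summarises probes into probe sets. The deposited values fit that scale, lying between 0.133 and 12.0 with nearly equal quartiles on the 4 arrays. Whether other arrays were normalized together with these 4 is not given in the sources used here. Cells with an EZH2 knockdown, which the series' design mentions, were not analysed here. Quantile normalization sets the distributions of all arrays equal, so a shift common to most genes would be removed, and values near the background compress differences between dim genes.

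Samples were grouped by their titles. The number of arrays, 2 per group, limits the precision: an exact permutation test of 2 against 2 cannot give a two-sided p below 0.333, so single genes were tested only in a model that pools the variance over genes. Of 53617 probe sets, 23558 carried 1 gene symbol in the platform annotation, 2155 carried several and were not named, and 27904 were unnamed here. Symbols were updated through their gene identifiers with a RefSeq gene table of assembly GRCh38.p14, in which 22271 of the single-symbol probe sets matched and 3 symbols changed; no coordinates are given, since the files name no genome build. Each of the 22109 genes was represented by its brightest probe set, by the mean of the 4 arrays; 618 genes had more than 1. Genes with a mean at or above the 30th percentile, a log2 signal of 2.34, were tested, which left 15476.

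The choices below were made before the data were examined. The difference between GSK126 and control was fitted per gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without an intensity trend and without a robust prior, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Tests were two-sided. Fold changes and 95% confidence intervals come from the same fit on the log2 scale, with no pseudocount. There were 38 fixed gene lists of interferon response, antigen presentation, polycomb complexes and targets, cell type markers, stress, metabolism and proliferation, holding 884 genes, of which 778 were on a probe set with 1 symbol and 646 were tested. The 37 lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists; camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera has only the 2 residual degrees of freedom of these arrays, so a call over 37 lists is hard to reach. The Th1 chemokine list, with 2 tested members, was tested apart from that family. The differences within set 1 and within set 2 were compared by Pearson's r across genes, as a description only.

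Genes are named by a rule with 3 parts. The first is 14 fixed genes, of which 1 is not reported here and the others are EZH2, EZH1, EED, SUZ12, CXCL9, CXCL10, CXCL11, IRF1, CIITA, HLA-DRA, CD274, KDM6B and DNMT1; CXCL11 lay under the signal filter. The second is the 12 genes with the largest difference in each direction past the adjusted threshold and with no overlap between groups, where open places are filled with genes at an unadjusted p under 0.05, given as values that did not pass. It leaves out non-coding RNAs by the start or end of their symbols (such as MIR, SNOR, RNU, RNA5 or LINC), which the older symbol RN5S196 escaped, and likewise unnamed reading frames, olfactory receptors, immune receptor segments, sex-specific genes and probe sets with several genes. The third is up to 4 members of each described list with the largest absolute difference. The gene and list tests were run on data simulated with the spread of these arrays: of 100 genes changed by 1 log2 unit 69% were called, and of 100 genes changed by 2 log2 units 96%, among 15476 genes and with 6 false calls. The 2 groups of changed genes were planted in the same run, which eases the adjusted threshold for both. Where fewer genes change, a smaller share would be called. In the real data 13 genes lay above 1 log2 unit and 5 below -1, and CXCL10, at 1.82, was not called in limma (adjusted p = 0.202). In 100 simulations without any shift, 0 of the 37 lists was called in any, and a shift of the interferon gamma list by 0.2 was called in 100 of 100. The simulated genes were independent of each other, so these runs do not show how the list tests behave with correlated genes.

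The alternatives were the set number as a replicate block, an intensity trend or a robust prior in eBayes, no filter or a filter at the 50th percentile, quantile normalization of the 4 arrays again, centring of each array on its median, the mean of a gene's probe sets, a threshold of 0.1, testing of all probe sets singly, the other set tests, a crossed pairing of the sets, and leaving out each array in turn.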

Results

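Gene expression was measured on 4 arrays of primary ovarian cancer cells, which are cells cultured from tumour tissue and are not an established line. The labels describe cells pretreated with GSK126 and given interferon gamma for 24 hours, and name 2 arrays GSK126 and 2 arrays control. GSK126 is a small molecule that inhibits the methyltransferase activity of EZH2, the enzyme that places the repressive H3K27 trimethyl mark. The same treatment text stands with all 4 samples, so the controls were taken as cells without GSK126, and whether they also received interferon gamma was not stated separately. No array marked as unstimulated was analysed here, and the interferon response itself was therefore not measured. The arrays are numbered as set 1 and set 2 within each group. A difference given for a set lies between same-numbered arrays, which are not known to be pairs, so another pairing can give other values. Nothing in the labels says whether the sets are separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. Each array held 53617 probe sets, with a median log2 signal between 2.74 and 2.76. Across all probe sets, Pearson's r was 0.985 between the control arrays, 0.985 between the GSK126 arrays, and 0.983 to 0.985 between arrays of different groups; these are correlations across probe sets, which are not independent replicates. The number of arrays limits the precision of every value below.

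The comparison asked which genes differ between GSK126 and control cells, and the study's title puts the question to the Th1 chemokines, the ligands of CXCR3 that attract T cells. CXCL10 had a signal of 4.91 ± 0.05 (log2, mean ± SD, n = 2) in control cells and 6.73 ± 0.13 (n = 2) with GSK126, a 3.53-fold higher level (95% confidence interval 2.88 to 4.33). CXCL9 had 5.68 ± 0.18 in control cells and 6.89 ± 0.31 with GSK126 (n = 2 each), a 2.32-fold higher level (1.68 to 3.20). For both genes the GSK126 arrays lay above both control arrays, with differences of 1.69 and 1.95 log2 units in sets 1 and 2 for CXCL10, and 0.87 and 1.56 for CXCL9. CXCL11, the remaining member, had means of 1.83 and 2.22, under the signal filter at 2.34, and was not tested. Neither tested gene passed 0.05 after Benjamini-Hochberg adjustment over all 15476 genes in limma (adjusted p = 0.202 for CXCL10 and 0.535 for CXCL9). Adjusted over the list alone, 2 of 2 passed (adjusted p = 2.61e-05 and 9.82e-04), but this list is the one named in the study's title and may have been chosen on these samples, so it is not independent evidence of its direction. The mean of the pair was 1.52 log2 units higher with GSK126, and limma's camera test of the pair against the other genes gave p = 2.13e-06 with a preset correlation and p = 0.0774 with an estimated correlation, while fry, which tests the pair against no difference, gave p = 0.00902.

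**Figure D1:**
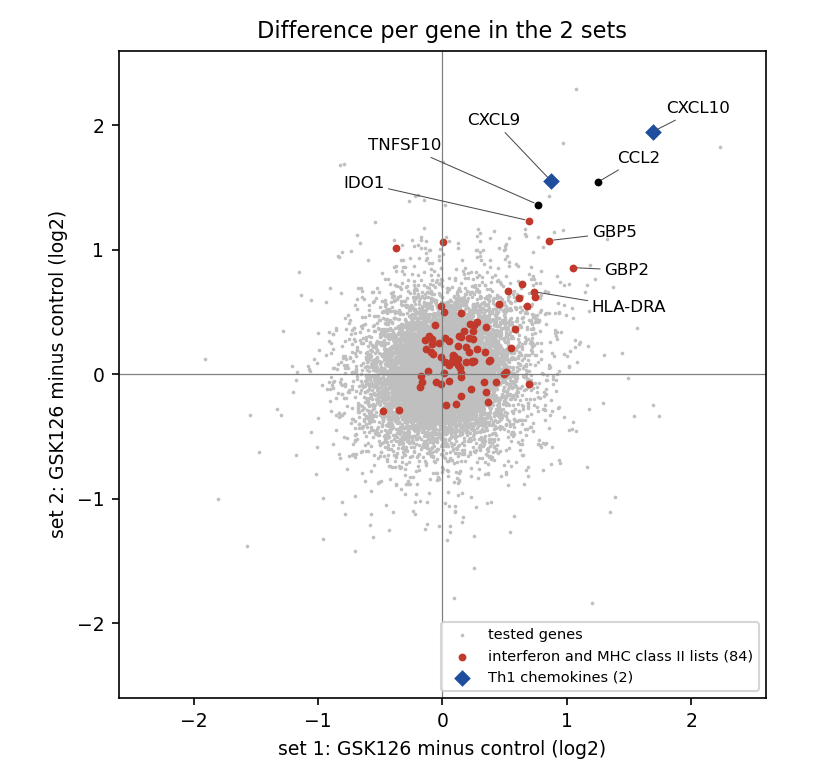
Each point is 1 tested gene, placed by its log2 difference between GSK126 and control in set 1 (x axis) and set 2 (y axis), with genes of the interferon gamma, type I interferon and MHC class II lists in red, the Th1 chemokines as blue diamonds, and CCL2 and TNFSF10 in black. CXCL10 lies at 1.69 and 1.95, and across all tested genes the differences of the sets had a Pearson's r of 0.134.

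Over all genes, 0 of 15476 passed an adjusted p of 0.05 in limma. With an intensity trend in limma's prior, 2 genes passed, CXCL10 (adjusted p = 0.00593, and 0.00593 to 0.732 over all alternatives) and GBP2 (0.0164, and 0.0164 to 0.784). At an unadjusted p under 0.05 there were 1226 genes, 676 higher and 550 lower with GSK126, where 774 would be reached by chance. Both GSK126 arrays lay above both control arrays in 3163 genes and below both in 2817, together 38.6% of the genes, against 33.3% by chance. A difference above 1 log2 unit was seen in 13 genes in the higher direction and 5 in the lower. The log2 differences of set 1 and set 2 had a Pearson's r of 0.134 across genes, and 54.7% of genes had the same sign in both; genes are not independent replicates. A gene's difference had a median SE of 0.12 log2 units.

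None of the genes named in this paragraph passed the adjusted test over all genes. Among the genes that the naming rule allows, they have the largest separation of means at an unadjusted p under 0.05 and no overlap between groups. That rule leaves out most small RNAs. After CXCL10, the genes higher with GSK126 were led by LGALS17A, a galectin pseudogene, at 1.68 ± 0.41 log2 units (± SE; 1.04 without Control replicate 2), and CCL2, a chemokine that attracts monocytes. CCL2 was at 7.78 ± 0.39 (SD, n = 2) in control cells and 9.17 ± 0.18 (n = 2) with GSK126, 2.63-fold higher (95% interval 1.81 to 3.82). TNFSF10, which encodes the death ligand TRAIL, was 2.09-fold higher (1.56 to 2.80), and MMP1, an interstitial collagenase, was 2.05-fold higher (1.60 to 2.62). The interferon-inducible GTPases GBP5 and GBP2 were 1.96-fold (1.52 to 2.51) and 1.94-fold (1.61 to 2.33) higher. IDO1, an enzyme that degrades tryptophan, was 1.95-fold higher (1.41 to 2.70), from a control signal of 2.63. The remaining higher genes were XIRP1, an actin-binding protein of muscle, at 1.15 log2 units, the pseudogene TREML5P at 1.02 and the lectin gene FCN2 at 1.00, the last pair with control signals of 1.89 and 1.96, under the signal filter, so the size of these differences is limited by the background.

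In the other direction, RN5S196 had a difference of -1.48 ± 0.16 log2 units (SE). Its symbol is of the 5S ribosomal RNA family, and whether it is a gene or a pseudogene was not given in the annotation used. Its GSK126 mean of 2.04 lay under the signal filter of 2.34, as did those of SLC25A2 (2.23) and ECSCR (2.29), so the size of these differences is limited by the background. PMP2, a myelin lipid-binding protein, had -0.94 ± 0.31, with -1.55 in set 1 and -0.33 in set 2. SPRR2A, a protein of the cornified envelope, had -0.91 ± 0.11, and MMP8, the neutrophil collagenase, -0.76 ± 0.21, with -0.45 without GSK126 replicate 1. Between -0.81 and -0.74 lay WDR4, the pseudogene FRG2DP, KU-MEL-3, the mitochondrial ornithine carrier SLC25A2, RNF44, ECSCR and the hair keratin-associated KRTAP10-8. Without GSK126 replicate 1, WDR4 was at -0.33 and KRTAP10-8 at -0.49, and without GSK126 replicate 2, WDR4 was at -1.28 and RNF44 at -0.41. KRTAP21-1 had -0.91 ± 0.15 on its brighter probe set and 0.32 on another, so its probe sets disagreed. The other ECSCR probe set was at 0.02, with a mean signal of 1.34, under the filter. A difference over 1 log2 unit in both sets was seen in 5 higher genes (CCL2, CXCL10, LGALS17A, MIR4295 and MIR548O2) and 2 lower ones (RN5S196 and SNORA12), of which the small RNAs were named after their values were seen.

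**Figure D2:**
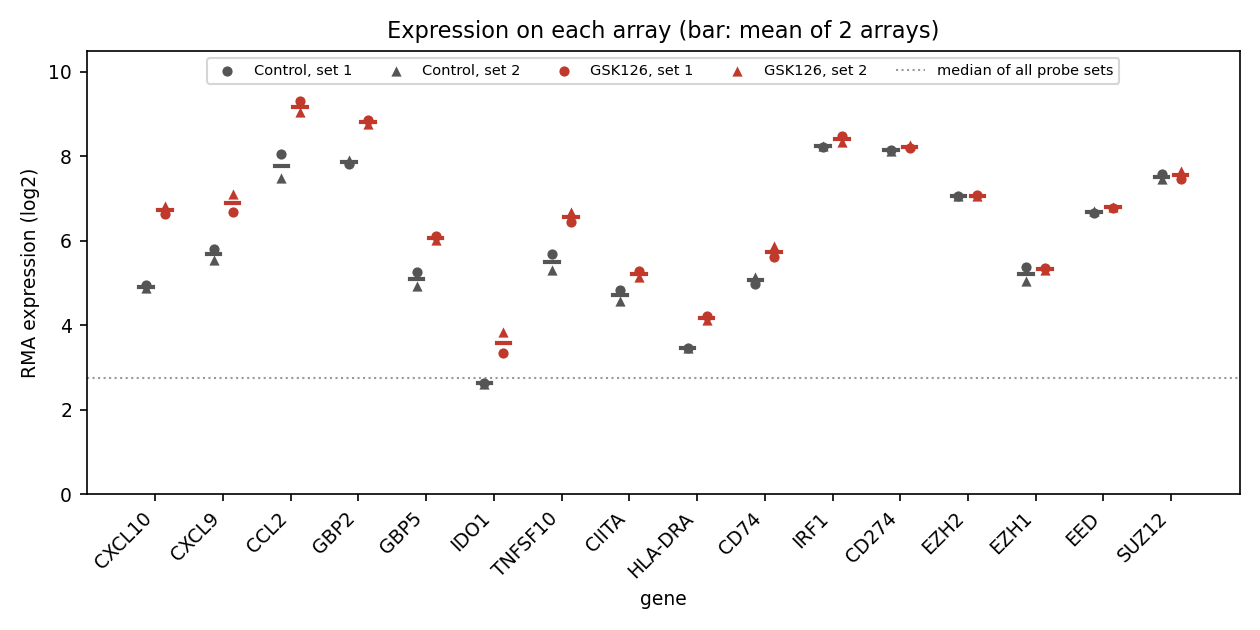
The log2 RMA signal of 16 genes (y axis) is drawn for each array, control in grey and GSK126 in red, set 1 as circles and set 2 as triangles, with a bar at the mean of the 2 arrays of a group and a dotted line at the median of all probe sets. For CXCL10, CXCL9, CCL2, GBP2, GBP5, IDO1, TNFSF10, CIITA, HLA-DRA and CD74 both GSK126 arrays lie above both control arrays, while EZH2 had a mean of 7.07 in both groups.

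Among the fixed gene lists, the interferon gamma core response had the smallest adjusted p in the camera test with the preset correlation. Of its 33 tested genes, 30 were higher with GSK126 and 3 lower, with a median difference of 0.17 log2 units; in 20 genes both GSK126 arrays lay above both control arrays and in 1 below, where chance gives 16.7% in each direction. After GBP5, IDO1 and GBP2, the next member by size was SOCS1, a feedback inhibitor of cytokine signalling, at 0.61 ± 0.11 (SE). The measured guanylate-binding protein genes GBP1, GBP2, GBP3, GBP4 and GBP5 each had separated groups, with differences of 0.60, 0.95, 0.35, 0.37 and 0.97; GBP1, GBP3 and GBP4 were named after their values were seen, and the sequence similarity of this family leaves open how far its probe sets are specific. The 3 lower members, also named after their values were seen, were SOCS3 at -0.32, ICAM1 at -0.06 and FAS at -0.05. Adjusted over the list alone, 5 genes passed (GBP2, GBP5, IDO1, SOCS1 and GBP1), and 0 passed over all genes. IRF1, the transcription factor induced early by interferon gamma, had 8.23 in control cells and 8.41 with GSK126, a difference of 0.18 ± 0.11 that ran from 0.11 to 0.25 without single arrays. In limma's camera test the list ranked above the other genes (adjusted p = 1.14e-06 over 37 lists, preset correlation), but not with an estimated correlation (adjusted p = 0.721). The latter form has 2 residual degrees of freedom, so its miss decides little, here and for the lists below. The fry test, which asks whether the list's genes move one way and makes no comparison with other genes, gave an adjusted p of 0.146.

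In the type I interferon response list, of 37 tested genes, 32 were higher and 5 lower with GSK126, the median difference was 0.12 log2 units, and the groups were separated upwards in 19 genes and downwards in 2. RSAD2, which encodes the antiviral protein viperin, differed by 0.68 ± 0.17 (SE), SAMD9L by 0.62 ± 0.10, TRIM22 by 0.38 ± 0.13 and IFI44L by 0.32 ± 0.13. SAMD9L alone passed when adjusted over the list alone (adjusted p = 0.0462), and 0 passed over all genes. The camera test gave an adjusted p of 1.08e-04 with the preset correlation, an adjusted p of 0.721 with an estimated correlation, and fry an adjusted p of 0.233.

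Genes of MHC class II presentation had a median difference of 0.21 log2 units, with 11 of 14 tested genes higher and 3 lower; the groups were separated upwards in 6 genes and downwards in 1. HLA-DRA was 1.62-fold higher (95% interval 1.36 to 1.94), from 3.47 to 4.17, and CD74, the invariant chain, was 0.68 ± 0.13 log2 units higher (SE). The other HLA-DRA probe sets were at 0.22 to 0.60 log2 units, all below the 0.70 of the brightest one used here. The protease gene CTSS differed by 0.53 ± 0.26, with 0.00748 in set 1 and 1.06 in set 2, and CIITA, the transactivator of class II genes, by 0.51 ± 0.13. HLA-DRA and CD74 passed when adjusted over the list alone, and 0 passed over all genes. The list passed the camera test with the preset correlation (adjusted p = 0.0271), but not with an estimated correlation (adjusted p = 0.721) or in fry (0.212). The call was also lost with a stricter signal filter (0.115), without Control replicate 1 (0.351) and without GSK126 replicate 1 (0.140), over an adjusted p range of 0.00526 to 0.721.

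**Figure D3:**
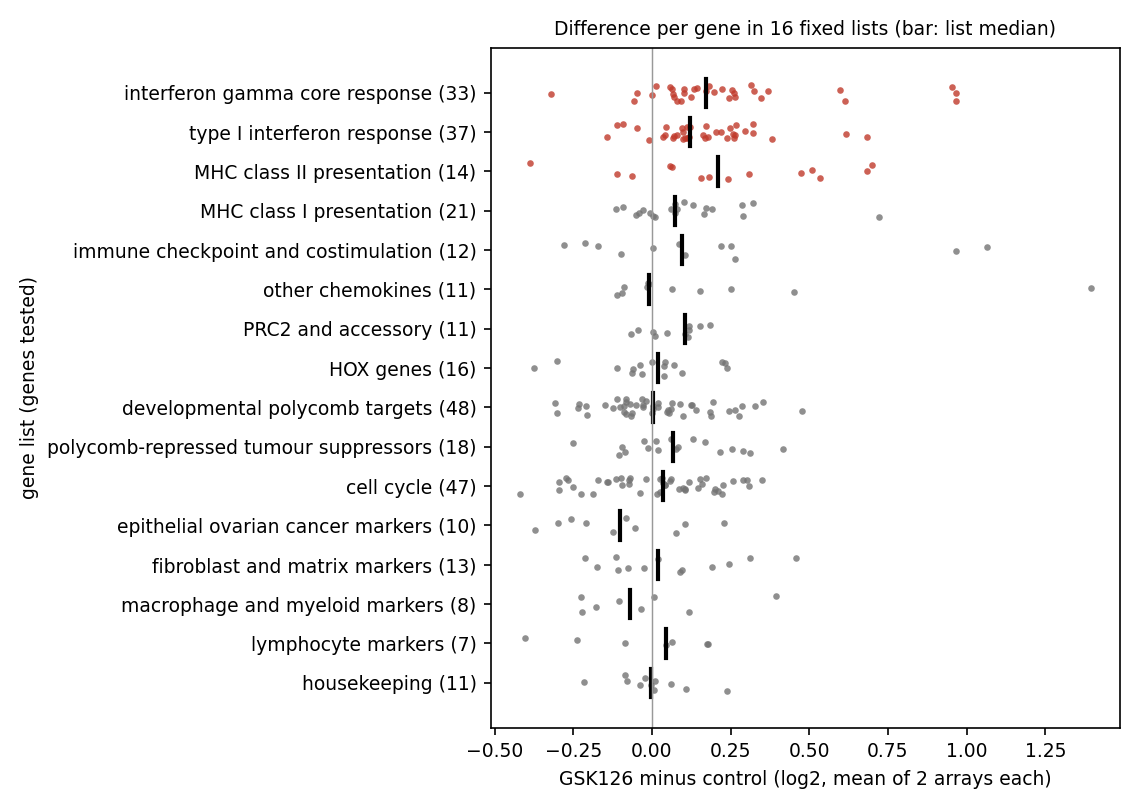
Each point is the log2 difference between GSK126 and control of 1 tested gene (x axis), in 16 of the fixed lists (y axis, number of tested genes in brackets), with a black bar at the list's median; red lists passed the camera test with the preset correlation and grey ones did not. The 3 red lists have medians of 0.17, 0.12 and 0.21. They passed neither with an estimated correlation, a form with 2 residual degrees of freedom and little power, nor in fry.

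The other 34 lists did not pass the camera test, and the smallest adjusted p among them was 0.170. MHC class I presentation had a median of 0.07 log2 units over 21 genes (adjusted p = 0.266), with PDIA3 at 0.72 ± 0.46 (SE; 1.69 in set 1 and -0.25 in set 2), TAPBPL at 0.32, HLA-C at 0.29 and HLA-F at 0.29. The other HLA-C probe sets were at 0.07 to 0.21 and the other HLA-F probe set at 0.08. The interferon receptor and JAK-STAT list had a median of 0.11 over 13 genes (adjusted p = 0.266), and 0.0425 to 0.111 without single arrays; beside SOCS1, its leading members were SOCS3 at -0.32, JAK2 at 0.25 (0.49 in set 1 and -3.98e-04 in set 2) and PTPN2 at 0.24. The immune checkpoint list had a median of 0.09 over 12 genes (adjusted p = 0.266), and 0.0347 to 0.140 without single arrays; beside TNFSF10 and IDO1, TNFRSF14 was at -0.28 and TNFSF9 at 0.26. CD274, which encodes PD-L1, had 8.14 in control cells and 8.23 with GSK126, a difference of 0.08 ± 0.10 that ran from 0.06 to 0.11 without single arrays. The list of other chemokines had a median of -0.01 but a mean of 0.18 over 11 genes (adjusted p = 0.475), its test pointing upwards like the mean; beside CCL2, CXCL16 was at 0.25, and CXCL2 at 0.45 and CXCL1 at 0.15 had overlapping groups. NF-kB targets and inflammatory cytokines had a median of 0.04 (adjusted p = 0.435), and 0.0468 to 0.0695 without single arrays. IL15 was at 0.70 ± 0.15 and IL1A at 0.32 (0.64 in set 1 and -0.01 in set 2).

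The target of the inhibitor, EZH2, had the same mean transcript level of 7.07 in both groups, a fold of 1.00 (95% interval 0.843 to 1.19) whose sign turned with 2 other scalings of the arrays. Its paralog EZH1 differed by 0.12 ± 0.14 log2 units (SE) and the complex partners EED and SUZ12 by 0.12 ± 0.10 and 0.05 ± 0.12. The signs of EZH1 and SUZ12 turned when single arrays were left out. The list of PRC2 and its accessory proteins had a median of 0.11 (adjusted p = 0.429), and 0.0401 without Control replicate 2, with LCOR at 0.18 and PHF1 at 0.15. The PRC1 list had a median of -0.05 (adjusted p = 0.435), with CBX6 at -0.45, PCGF2 at -0.31, PHC3 at 0.27 and RING1 at -0.16 (-0.32 in set 1 and 0.00 in set 2). Among other chromatin modifiers, the H3K27 demethylase genes KDM6A and KDM6B were at 0.45 ± 0.12 and -0.11 ± 0.13, HDAC9 was at 0.36, TET3 at -0.30, UHRF1 at -0.27 and the DNA methyltransferase gene DNMT1 at -0.08 ± 0.11 (-0.14 to -0.02 without single arrays); this list's median was -0.03 and its mean 0.01 (adjusted p = 1.00). KDM6B's sign turned without Control replicate 2.

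Lists of genes known to carry the polycomb mark in many tissues were centred near 0 among the genes that passed the signal filter. The filter left 16 of 24 measured HOX genes, 18 of 26 tumour suppressors and 48 of 67 developmental targets. These 48 had a median control signal of 2.95, near the array median of 2.75, where differences are compressed. A change of silent targets could therefore not be judged. The groups were separated upwards in 10 of these 48 genes (20.8%) and downwards in 2, against 3163 and 2817 of all 15476 tested genes. The HOX list had a median of 0.02 log2 units, a mean of -8.35e-05 and a test pointing downwards (16 genes, adjusted p = 0.943). Its leading members were HOXC11 at -0.37, HOXC10 at -0.30, HOXB4 at 0.24 and HOXD8 at 0.23. HOXB4 and HOXD8 differed by 0.47 and 0.43 in set 2 and by 0.01 and 0.03 in set 1, values that depend on how the arrays are paired. The developmental polycomb targets had a median of 0.00 over 48 genes (adjusted p = 0.943), a value whose sign turned with 2 other scalings; TWIST1 was at 0.48 ± 0.19 (SE), FOXD1 at 0.35, MSX2 at 0.33 (0.07 in set 1 and 0.59 in set 2) and MEIS1 at -0.31 (0.0958 in set 1 and -0.715 in set 2). Tumour suppressor genes described as polycomb-repressed had a median of 0.07 over 18 genes (adjusted p = 0.429), with RASSF1 at 0.42 ± 0.11, DACT3 at 0.31 (0.00 in set 1 and 0.62 in set 2), CDKN1A at 0.29 and KLF2 at 0.25. The cell cycle list had a median of 0.03 over 47 genes (adjusted p = 0.806); MCM5 was at -0.42, MKI67 at 0.35, CDC25C at 0.31 and CENPE at 0.30.

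Markers of the cell types a tumour culture can hold did not pass the test in either direction. Epithelial ovarian cancer markers had a median of -0.10 log2 units over 10 genes (adjusted p = 0.266), with WFDC2 at -0.37 (-0.64 in set 1 and -0.10 in set 2), MUC16 at -0.30, CLDN3 at -0.26 (-0.02 and -0.50) and KRT8 at 0.23 (-0.00214 and 0.46). Macrophage and myeloid markers had a median of -0.07 over 8 genes (adjusted p = 0.592). Lymphocyte markers had a median of 0.05 and a mean of -0.04 over 7 genes, with a test pointing downwards (adjusted p = 0.820). Fibroblast and matrix markers had a median of 0.02 (adjusted p = 0.592), with ACTA2 at 0.46 ± 0.12 (SE) and COL6A3 at 0.31, and endothelial markers a median of -0.05 (0.998). Mesothelial markers had a median of -0.04 and a mean of 0.06, with a test pointing upwards (adjusted p = 1.00), and the epithelial-mesenchymal transition list had a median of 0.02 (0.592). The housekeeping and ribosomal protein lists had medians of -0.00446 (adjusted p = 0.998) and -0.04 (0.266).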

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

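The interferon gamma and type I lists without genes shared with other lists, and the MHC class II list without HLA-DRA and CIITA, were tests chosen only after the result was seen; the other alternatives were planned. The count of genes past the adjusted threshold stayed at 0 in every alternative but the intensity trend, which gave 2; this holds at a threshold of 0.1, for all probe sets singly and for each array left out. The count at an unadjusted p under 0.05 ran from 935 to 1541 over the alternatives. The alternatives were run on single genes for the 34 tested genes of the fixed set and of the largest differences, not for genes named only as list members; of 399 such comparisons, 389 kept direction and side of the threshold, 2 newly passed it (CXCL10 and GBP2 under the trend) and 8 turned sign, in EZH2, EZH1, SUZ12 and KDM6B. A fit without 1 array leaves its group with 1 sample, assumed to vary like the other group. With the set number as a replicate block, 0 genes passed and 3 lists passed, the same counts as without it; the deviations of same-numbered arrays from their group means had a correlation of 0.00186, the numbers come with no statement of a shared culture, and the sets were therefore not treated as pairs. The number of arrays and, for dim genes, the signal over background limit the values.

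With an estimated correlation 0 lists passed camera, and in fry 0 passed after adjustment. The medians stay 0.171 (interferon gamma), 0.122 (type I) and 0.211 (MHC class II) by construction. The estimated correlations of these lists were -0.0126, 0.0427 and -0.0602, against the preset 0.01. A correlation above the preset value therefore cannot have removed the interferon gamma and MHC class II calls in camera. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom of these arrays. With the preset correlation it uses a number set by the genes. So few degrees of freedom make a call over 37 lists hard to reach, so the lost calls in camera do not show an absent shift. Why the lists missed the threshold in fry was not tested. The Th1 pair, at 1.52, also missed 0.05 with an estimated correlation. Without single arrays 2 to 3 lists passed. The MHC class II list missed the threshold with the 50th percentile filter, which leaves 9 of its genes (median 0.182 log2 units). It also missed it without HLA-DRA and CIITA (median 0.169), and in the fits without Control replicate 1 or GSK126 replicate 1. Its median ran from 0.126 to 0.301 without single arrays. The interferon gamma list had medians of 0.135 to 0.215 log2 units and the type I list of 0.104 to 0.185 without single arrays, past the threshold each time. The correlation of the sets was 0.0985 without a filter and 0.209 with the 50th percentile filter. The senescence secretory and solute carrier lists passed camera only with the 50th percentile filter (adjusted p = 0.00139 and 0.0184), with medians of 0.157 and 0.126 log2 units.

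Signs turned for values near 0, and the cause was not tested. EZH2 was at -0.00312 after quantile normalization, at -0.00237 after centring, and at -0.0121 to 0.0162 without single arrays. EZH1 ran from -0.0426 to 0.281, SUZ12 from -0.0478 to 0.146 and KDM6B from -0.255 to 0.0378 without single arrays. Without a filter the tumour suppressor list was at -1.62e-04 and the lymphocyte list at -0.0117. After quantile normalization the developmental list was at -0.00982 and oxidative phosphorylation at 0.0128, after centring the developmental list was at -0.00221, and with the mean of probe sets the heat shock list was at 0.00542. Without single arrays the list medians ran from -0.00446 to 0.127 (other chemokines), -0.0473 to 0.0384 (other chromatin modifiers), -0.0376 to 0.0163 (p53 targets), -0.0971 to 0.0291 (apoptosis), -0.110 to 0.0338 (heat shock), -0.0489 to 0.0251 (oxidative phosphorylation), -0.0141 to 0.0186 (housekeeping), -0.00895 to 0.0664 (developmental), -0.0399 to 0.0885 (cell cycle), -0.187 to 0.138 (mesothelial), -0.104 to 0.161 (lymphocyte), -0.0821 to 0.0291 (endothelial), -0.0184 to 0.110 (cancer-testis), -0.00392 to 0.133 (tumour suppressors) and -9.11e-04 to 0.0507 (HOX). Some lists kept their sign without single arrays but moved in size: cholesterol synthesis ran from -0.132 to -0.00209, glycolysis from 0.0193 to 0.1004, fibroblast markers from 0.0146 to 0.0831, myeloid markers from -0.0876 to -0.00936, ribosomal proteins from -0.0699 to -0.0161, TGF-beta from 0.0580 to 0.132, epithelial markers from -0.128 to -0.0653, the integrated stress list from 7.16e-04 to 0.0102 and the epithelial-mesenchymal list from 0.00529 to 0.0243.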

Other observations

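The tests of leucocyte markers and of other splits of the arrays were chosen only after the result was seen. Further gene groups did not pass the camera test at an adjusted p of 0.05, and none of their genes passed over all genes; the members with the largest differences are given as values. The senescence secretory list had a median of 0.15 log2 units over 11 genes (adjusted p = 0.170), and 0.0812 to 0.187 without single arrays, with 0.22 in set 1 and -0.00833 in set 2, led by CCL2 and the collagenase MMP1, which passed when adjusted over the list alone, while IGFBP3 was at -0.25 and IGFBP6 at 0.22, with overlapping groups. Among immediate early and heat shock genes, JUN was 0.68 ± 0.14 (SE) higher, while MYC was at -0.38 ± 0.10, EGR1 at -0.33 ± 0.10 and FOS at -0.32 ± 0.14, around a list median of -0.01 (adjusted p = 0.607). The stress-responsive factor ATF3 was at 0.56 ± 0.13, PSAT1 of serine synthesis at -0.35, the cystine carrier SLC7A11 at 0.30 (0.60 in set 1 and -0.00734 in set 2) and CEBPB at 0.26, in an integrated stress list with a median of 0.03 (adjusted p = 0.970). The solute carrier and drug efflux list had a median of 0.11 (adjusted p = 0.266), and 0.0278 to 0.145 without single arrays, with the efflux pump ABCG2 at 0.42 ± 0.12, the glutathione synthesis gene GCLM at 0.38 and the metallothioneins MT1X and MT1E at 0.37 and -0.38. The TGF-beta and BMP list had a median of 0.10 (adjusted p = 0.266), with ID1 at 0.35, PMEPA1 at 0.35 and GREM1 at 0.22. The complement list had a median of 0.11 (adjusted p = 0.298), and 0.0410 to 0.170 without single arrays, with CFD at -0.53 ± 0.24 (-0.97 in set 1 and -0.09 in set 2) and SERPING1 at 0.32 ± 0.10.

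Metabolic lists lay close to 0. Lipid synthesis had a median of -0.05 (adjusted p = 0.480), and -0.0750 to -0.0478 without single arrays. The lipid droplet gene PLIN2 was at 0.40, ME1 at 0.38, ACSL1 at -0.36 and GPAM at -0.35. Glycolysis and hypoxia had 0.05 (adjusted p = 0.266), with VEGFA at 0.37 (0.67 in set 1 and 0.07 in set 2), PGAM1 at -0.35 and the glucose carrier SLC2A1 at 0.35. Cholesterol synthesis had -0.02 (adjusted p = 0.435) and 14 of 18 genes lower, with STARD4 at 0.26 (0.09 in set 1 and 0.42 in set 2) and SREBF2 at -0.20. Oxidative phosphorylation had -0.01 (adjusted p = 0.836), a sign that turned after quantile normalization. The p53 target list had -0.02 (adjusted p = 0.875), the apoptosis list -0.02 with a mean of 0.00 and a test pointing downwards (0.998), with BID at -0.34, and the cancer-testis list 0.02 (0.998), with MAGEA1 at -0.35 from a control signal of 6.09. Of the 20 epithelial ovarian cancer markers 10 lay under the signal filter, which is itself below the array medians. Among these, named after their values were seen, EPCAM had a control mean of 1.64, PAX8 1.95, KRT7 2.01, CDH1 2.05 and KRT19 2.18. The other 10 lay above the filter, and those with the largest differences had control means of 4.64 (CLDN3), 4.45 (KRT8), 3.09 (WFDC2) and 2.85 (MUC16).

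The interferon gamma and type I interferon lists passed the camera test with the preset correlation only. With an estimated correlation, which leaves camera 2 residual degrees of freedom, the adjusted p was 0.721 for both, and in fry 0.146 and 0.233. Leucocytes carried along in the GSK126 cultures could raise such genes. The 15 tested macrophage and lymphocyte markers had a median difference of -0.0337 log2 units. Resampling the markers gave a 95% bootstrap interval of -0.222 to 0.119, which covers the spread among markers and none between samples. The markers had a median signal of 2.84, near the array median of 2.75, and 2 of them lay above the upper quartile of 4.56. Most were thus too dim to exclude a small share of such cells. A chance split of the arrays stays open as well, because 4 arrays allow 3 splits: 1 of 3, the real one, gave a mean of the interferon gamma list as large as 0.238, the highest other was 0.0241, and this is too few splits for a share under 0.05. An effect of GSK126 on interferon-inducible genes is the explanation the design names and was not tested apart from these.

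The count of genes at an unadjusted p under 0.05, 1226, was the largest of the splits, so 1 of 3 splits gave as many, and the highest other gave 687; these are too few splits for a share under 0.05.

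Before its test was run, the idea that interferon-inducible genes with a lower control signal differ more with GSK126 was written down as a hypothesis, to be tested with control signal from one set and difference from the other. Over 106 interferon and antigen presentation genes, the mean Spearman's rho across genes was -0.119 (SE 0.0739 from a bootstrap over genes), made of -0.00657 and -0.232. Random lists matched on signal gave -0.186 to 0.107 in their central 95%, and the observed value, at percentile 15.3, did not leave that range. A value above the lower end of that range was the outcome written down beforehand as speaking against the hypothesis, and it was met. By the rule as first written, the hypothesis therefore failed. The value lay within 1 SE of that end, and counting such a value as undecided was a rule added after it was seen; by that rule the hypothesis stays open. A second hypothesis, that neighbouring genes of unlike names move together with GSK126, found no match in the data. The correlation of differences between 12173 adjacent protein-coding pairs was 0.0239 (SE 0.00906), against 0.0263 and 0.00964 for the other splits of the arrays. Pairs whose symbols begin alike were left out, so neighbouring members of a gene family, such as chemokine or guanylate-binding protein genes, were not compared.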
